A study of Danio rerio with 4 samples.

How the data were processed

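Gene expression in whole zebrafish embryos was compared on 4 arrays with 2 colours each. Per the labels, NHA9 embryos came from a cross of a line carrying NUP98-HOXA9 behind a floxed eGFP cassette under the spi1 promoter with a line carrying Cre under the hsp70 promoter. The lGl embryos came from the same floxed line crossed to wild-type AB fish, so their cassette stayed in place. Both kinds of embryo received a heat shock of 37 °C for 1 hour at 24 hours of age, were held at 28 °C, and gave RNA at 28 hours of age, 4 hours after the heat shock. Per the labels, there were 2 RNA extracts of each kind. The extracts were paired by replicate number, and each pair was hybridised once with NHA9 in Cy5 (forward) and once with the dyes exchanged (dye swap). The labels call the extracts biological replicates but do not give the number of embryos or clutches behind each. In the main fit, p-values rest on the spread between these 2 pairs of extracts, pooled over all genes.

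Per the labels' protocols, RNA was purified with Trizol and RNeasy columns, cDNA was labelled directly with Alexa Fluor dyes, and samples low in RNA were amplified. Which samples were amplified is not stated. The values used here are the authors' deposited log ratios of the 2 channels of each array, 20406 probes per array with no missing value, taken as log2. The log base, the centring and the direction of the deposited ratios are not given in the sources used here, and neither are the scanner, the background correction, the normalization and any probe filter. The base was taken as log2 because values reached from −7.98 to 6.75, too wide a range for a log10 ratio. That range does not exclude a natural log, so fold changes stated here hold only if the base is 2. Column medians were −0.01 and −0.01 for the forward arrays of replicates 1 and 2, and 0.03 and 0.03 for their dye swaps. Spot intensities were not used here, so signal over background is unknown, and the precision stated here rests on the 2 pairs of extracts.

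The direction of the columns was examined by a rule fixed before the data were examined. If the columns had been deposited by dye, an array and its dye swap would run opposite to each other. As deposited, they correlated positively over all probes (r = 0.747 in replicate 1 and 0.465 in replicate 2; probes are not independent replicates). By the rule, values above 0.3 in both pairs meant that the columns had already been turned to a single contrast or that a dye effect dominated, and that both readings were to be given, with no direction claimed from one alone. The planned fit turned the swap columns by their dyes. The account below instead reads all 4 columns as a single contrast, with the planned reading by dye given beside it. This choice was made after the correlations were seen. It rests on ratios as large as 7.61 in the mean of all 4 columns, against at most 1.82 in the difference between orientations, and on the shared part holding 52.1% of the variance over probes against 18.3%. Each forward array correlated less with the dye swap of the other replicate (r = 0.112 and 0.109) than with its own. A dye effect alike in both replicates would not give that difference, which argues against it as the only source of the shared part. Arrays of the same orientation also correlated between the replicates (r = 0.449 for forward arrays, 0.387 for dye swaps). For arrays that differed in both orientation and replicate, rank correlations were −0.012 and 0.009. A part that depends on orientation was thus alike in both replicates, which either reading allows. A dye effect that differed between the replicates was not excluded, so the directions stated here hold for the chosen reading. In it, NHA9 over lGl is the likely direction, since the forward arrays are titled NHA9 against lGl and carry NHA9 in Cy5. If the deposited ratio is lGl over NHA9, every sign turns.

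Probes were named through a table of the array platform's annotation, with symbols updated through RefSeq's gene table for assembly GRCz12tu. Of the 20406 probes, 16810 had 1 symbol, 0 had several and 3596 stayed unnamed. Symbols were matched by accession for 14620 probes, by current symbol for 1676, by synonym for 506, and kept from the platform table for 8. Probes of a gene were averaged, which gave 9665 named genes, and the 3596 unnamed probes were tested as single items, 13261 in all. Array coordinates were not used, and the RefSeq table served only for names and for which genes neighbour each other.

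An array and its dye swap share the same 2 extracts, so they were averaged to 1 replicate (n = 2). The mean of the 2 replicates was tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on adjusted p. limma estimated infinite prior degrees of freedom, so all genes shared a pooled SD of 0.43 and a standard error of 0.30, and the 95% interval of each log2 ratio was ±0.59. Each p-value therefore followed from the mean ratio alone, whatever the spread of the gene's own 2 replicates. An SD given with a gene is that of its own 2 replicate values. Genes with a mean change of at least 2-fold and one sign on all 4 columns were counted without a test. A total of 24 gene lists fixed before the data were examined, each with at least 5 measured members, were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. The last 2 had 1 residual degree of freedom, so hardly any list could pass them. Failing them does not argue against a list. All 69 ribosomal protein genes differed in one direction between dye orientations, yet camera with an estimated correlation gave an adjusted p of 0.948. Estimated correlations reached 0.60. Among the lists that passed camera they ran from 0.05 (DNA damage and apoptosis) to 0.59 (nervous system), all above the preset 0.01. The p-values from that preset may therefore be too small for these lists, most of all for the nervous system. The replicate block fits used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9.

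The code was tested on simulated data with the pooled spread of this comparison, 13261 genes and 200 of them changed, in 20 simulations. Genes were drawn independently and with one common spread, as the fit assumes. The fit recovered 5.3% of genes changed 1.5-fold, 41.7% of those changed 2-fold, and 100% of those changed 4-fold or 8-fold, and 4.3% of its calls were false. These rates check the code and need not carry over to the data, where the replicates of 35 called items lay over 2 apart.

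The genes named in the text were chosen by a rule fixed before the data were examined. It took the 12 named genes with the largest positive and the 12 with the largest negative mean among those past the threshold with one sign on all 4 columns. It added up to 4 members of each list, called ones first, and a fixed set of spi1, meis1, dnmt1, ptgs, hsp70l, gata1a, mpx, lcp1 and runx1 genes, and a further gene that is not reported here. No probe used here was named runx1, so it was not analysed here. Genes named outside the rule appear only in the closing part, as chosen after their values were seen. Alternatives tried were centring, scaling and quantile normalization of arrays, each probe as its own item, the median of a gene's probes, either dye orientation alone, the reading by dye, other fits of the 4 arrays, other thresholds, other list tests, and leaving out each replicate.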

Results

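Transcript ratios between NHA9 and lGl embryos were measured at 28 hours post-fertilization on 4 arrays of 20406 probes. NHA9 embryos carry NUP98-HOXA9, a fusion oncogene of human myeloid leukaemia, and express it from the myeloid spi1 promoter once Cre has removed an eGFP cassette. In lGl embryos the cassette is intact. Both kinds were heat-shocked, but only the NHA9 cross had a Cre-carrying parent, while the lGl cross had an AB parent. There were 2 pairs of RNA extracts, each measured in both dye orientations and counted as 1 replicate. The comparison asked how expression in the whole embryo differed with the activated fusion gene 4 hours after heat shock. Cre and the second parent differed between the crosses together with the fusion gene. Their effects cannot be told apart for any gene or list given here. Ratios are given as NHA9 over lGl, which is the likely direction from the array titles and dyes and is not stated with the values. They treat the 4 columns as already turned to that contrast, and a reading by dye is given further on.

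The highest ratios in NHA9 embryos were those of si:dkey-22i16.7 at 3.77 ± 0.86 on the log2 scale (SD, n = 2; limma adjusted p = 1.59e-32), and of f7i, a coagulation factor VII relative, at 3.33 ± 0.45. They were followed by isca1, an iron-sulphur cluster assembly gene, at 3.21 ± 0.47, and by si:ch211-191j22.3 at 3.18 ± 0.85. The autophagy gene atg14 was higher by 3.04 ± 0.86 and the fatty acid receptor gene cd36 by 3.03 ± 0.90. The gene cyp11a1.1, which encodes the side-chain cleavage enzyme that starts steroid synthesis, stood at 2.96 ± 0.13, 3.05 in replicate 1 and 2.87 in replicate 2. LOC100002392 was at 2.73 ± 0.29, the polymerase III factor gene brf1a at 2.41 ± 0.96, ggact.2 at 2.4 ± 0.20 and the palmitoyltransferase gene zdhhc3b at 2.38 ± 0.92. The mitochondrial ribosomal gene mrps7 averaged 2.5 ± 1.54, but was 1.42 in replicate 1 and 3.58 in replicate 2. One sign on all 4 columns was a condition for naming these 12, and the weakest adjusted p among them from limma was 1.35e-12, for zdhhc3b. Only f7i, isca1 and si:ch211-191j22.3 had 2 probes, and the others rest on 1 probe each. With the replicate as a block and no dye term, mrps7 no longer passed (limma adjusted p = 0.128), and the adjusted p of si:dkey-22i16.7 was 0.00338.

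The lowest ratio of a named gene was that of zgc:173443 at −4.54 ± 0.58 (SD, n = 2; limma adjusted p = 2.01e-47). The 2 measured genes that precede it in assembly GRCz12tu were also lower, si:ch211-251f6.7 at −3.46 ± 0.44 and zgc:136254 at −1.54 ± 0.49. LOC794425 was lower at −3.34 ± 0.26 and fkbp16, of the FK506-binding family, at −2.51 ± 0.98. Lower ratios in NHA9 embryos also included spry1, an inhibitor of receptor tyrosine kinase signalling, at −1.54 ± 0.74 and the RNA exosome gene exosc1 at −1.53 ± 0.69. For several lower genes a single replicate held most of the change. The HSP90 co-chaperone gene ahsa1a was at −2.61 in replicate 1 and −0.73 in replicate 2, the cytokine subunit gene ebi3 at −2.32 and −0.68, si:ch211-132b12.1 at −3.21 and −1.48, and spry1 at −2.06 and −1.01. The plasminogen receptor gene plgrkt was at −0.98 and −2.90, and the ubiquitin ligase gene rnf146 at −0.76 and −2.23. One sign on all 4 columns was again a condition, and the limma adjusted p of the 12 lower genes was at most 7.09e-05. Only si:ch211-251f6.7, si:ch211-132b12.1 and rnf146 (2 probes each) and plgrkt (3 probes) had more than 1 probe. With the replicate as a block and no dye term, plgrkt, ahsa1a, zgc:136254, spry1, exosc1, ebi3 and rnf146 no longer passed (limma adjusted p from 0.0545 to 0.138). The adjusted p of zgc:173443 in that limma fit was 0.000428.

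**Figure D1:**
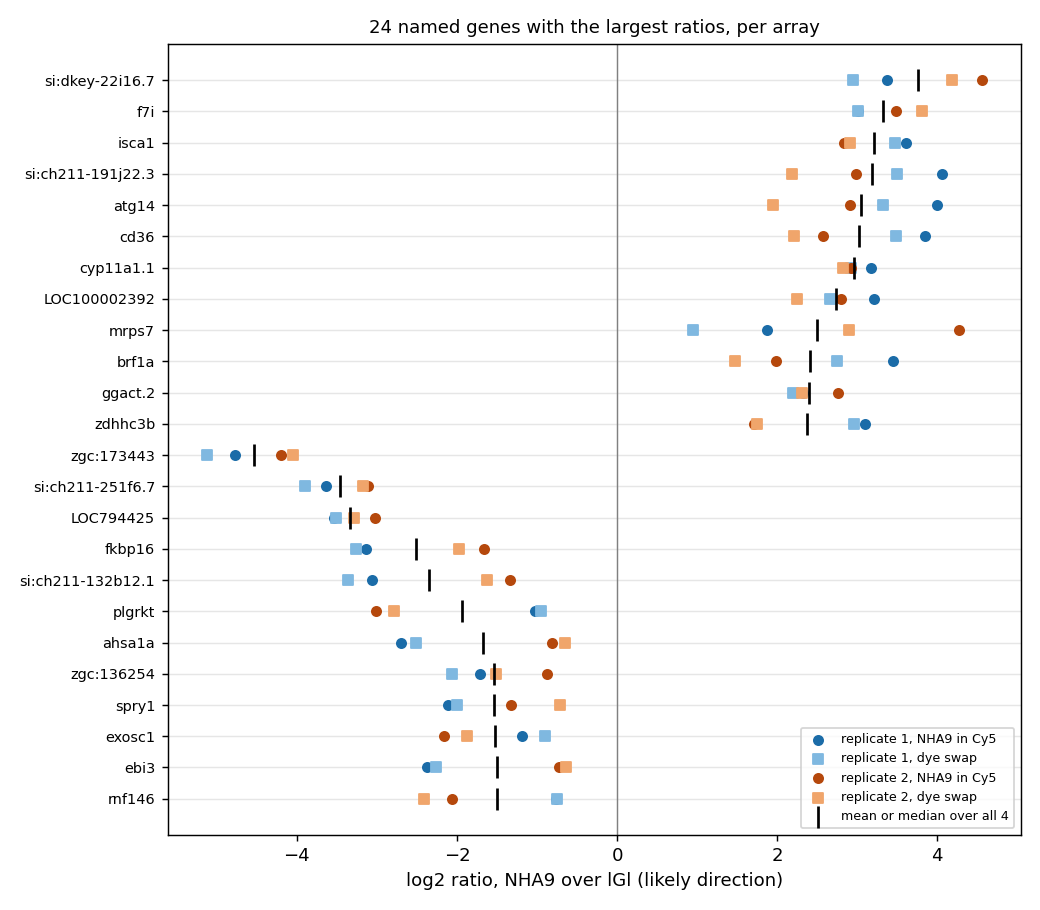
Log2 ratio of NHA9 over lGl (x axis) for the 12 named genes with the highest and the 12 with the lowest mean ratios, with a point for each of the 4 arrays and a bar at the mean. Every gene lies on 1 side of 0 on all 4 arrays, as its selection required. Means run from zgc:173443 at −4.54 to si:dkey-22i16.7 at 3.77, while mrps7, plgrkt and ahsa1a show wide gaps between replicates.

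Over all 13261 items tested with limma, 376 passed an adjusted p of 0.05, of which 271 were higher and 105 lower in NHA9 embryos. Of these, 225 were named genes (164 higher, 61 lower) and 151 were unnamed probes. All 4 columns had one sign for 348 of the 376. Only 70 of the 376 had 2 or more probes, so most calls rest on 1 probe. A change of at least 2-fold with one sign on all 4 columns was seen for 310 items, 229 higher and 81 lower. Taken alone, replicate 1 held 543 items of that size with one sign on its 2 columns, and replicate 2 held 756. At an unadjusted p under 0.05 there were 1384. The 2 replicates correlated weakly over genes (r = 0.339, rho = 0.208; genes are not independent replicates) and shared a sign for 55.3% of them. The smallest ratio called was 0.96 in size on the log2 scale. In data simulated under its own assumptions the fit recovered 5.3% of genes changed 1.5-fold. The count was 248 with a dye term and the replicate as a block, 114 with that block and no dye term, and 243 with arrays scaled to a common spread. With dye-swap arrays alone 260 were higher and 248 lower.

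Of 18 measured macrophage and pan-leukocyte genes, 2 were higher in NHA9 embryos and 16 did not pass. The list passed camera with an adjusted p of 0.000192 in limma, but not with an estimated correlation (p = 0.237, adjusted p = 0.988). With 1 residual degree of freedom, hardly any list could pass the latter. In all, 17 had positive ratios and 14 were positive on all 4 columns, with a median of 0.55 (0.64 in replicate 1, 0.47 in replicate 2). Past the threshold in limma were mpeg1.1, a perforin-like macrophage gene, at 1.08 ± 0.17 (n = 2; adjusted p = 0.0158), and the amino acid transporter gene slc7a7 at 1.16 ± 0.75 (adjusted p = 0.0064). The ratio of slc7a7 was 0.63 in replicate 1 and 1.69 in replicate 2. Of the others, fcer1gl was at 0.88, arhgdig at 0.77 and lcp1, the L-plastin gene, at 0.56, none past the threshold. The promoter used for the transgene belongs to a gene of this list, and spi1b was at 0.46 (0.36 and 0.55) and spi1a at 0.47 (0.71 and 0.23), neither past the threshold. Adjusted over the list alone, 4 genes passed. With the replicate as a block and a dye term, slc7a7 no longer passed (limma adjusted p = 0.0605), and without a dye term mpeg1.1 did not either (adjusted p = 0.0761). With dye-swap arrays alone slc7a7 was at 0.709 and did not pass (adjusted p = 0.244).

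Of 12 neutrophil and granulocyte genes, 3 were higher, 9 did not pass and 0 were lower. The called genes were the collagenase gene mmp13a at 1.18 ± 0.94 (limma adjusted p = 0.00546, n = 2), the lysozyme gene lyz at 1.16 ± 0.24 (adjusted p = 0.0067) and the myeloperoxidase gene mpx at 1.04 ± 0.31 (adjusted p = 0.0251). mmp13a was at 1.84 in replicate 1 and 0.51 in replicate 2, and mmp9 at 0.92 did not pass. The list median was 0.48, but 0.45 in replicate 1 and 0.09 in replicate 2. Adjusted over the list alone, 5 genes were higher and 1 was lower. Of the 5, 1 was at 2.16 in replicate 1 and −0.35 in replicate 2, and the lower gene did not keep one sign on all columns. The list passed camera at an adjusted p of 0.022, and had p = 0.331 with an estimated correlation (adjusted p = 0.988). With the replicate as a block and a dye term none of the 3 genes passed in limma, with adjusted p of 0.0563 (mmp13a), 0.0776 (lyz) and 0.0642 (mpx). lyz was at 1.71 and 1.95 on forward arrays but at 0.94 and 0.03 on dye swaps, and with dye swaps alone its mean of 0.484 did not pass (adjusted p = 0.559). With forward arrays alone mpx did not pass (adjusted p = 0.0559).

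Among 15 interferon and inflammation genes, 12 had positive ratios and 2 passed. These were fosab, an immediate early transcription factor gene, at 1.33 ± 0.47 (limma adjusted p = 0.000785, n = 2), and the interferon-induced gene isg15 at 1.07 ± 0.92 (adjusted p = 0.0168). isg15 was at 0.42 in replicate 1 and 1.73 in replicate 2. The complement gene c3a.1 and the cytokine gene il34 were at 0.60 and 0.61, not past the threshold. The list median was 0.32, with 2 genes past the threshold over the list alone. Camera gave an adjusted p of 0.022, and p = 0.25 with an estimated correlation (adjusted p = 0.988). With forward arrays alone camera's adjusted p was 0.0792, and with the replicate as a block and a dye term isg15 no longer passed (limma adjusted p = 0.0724). Nor did isg15 pass with forward arrays alone (adjusted p = 0.105).

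Of 33 genes of the DNA damage response and apoptosis, 22 had positive ratios and 2 passed. bbc3, which encodes the pro-apoptotic protein Puma, was at 1.46 ± 1.55 (limma adjusted p = 0.000123, n = 2) and the initiator caspase gene casp8 at 1.02 ± 1.14 (adjusted p = 0.0288). Replicate 2 carried both: bbc3 was at 0.36 in replicate 1 and 2.56 in replicate 2, and casp8 at 0.22 and 1.82. phlda3 and sesn3, at 0.84 and 0.72, did not pass. The median of the list was 0.19, with 0.13 in replicate 1 and 0.33 in replicate 2, and 2 genes passed over the list alone. Camera's adjusted p was 0.0452, with p = 0.314 under an estimated correlation (adjusted p = 0.988). It was 0.0543 with arrays scaled to a common spread and 0.0966 with forward arrays alone. With the replicate as a block, casp8 no longer passed with a dye term (limma adjusted p = 0.124), nor bbc3 without one (adjusted p = 0.24). With dye-swap arrays alone casp8 did not pass (adjusted p = 0.0779).

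Of 48 measured genes of the HOX clusters and their cofactors, 36 had negative ratios and 0 passed, over all genes or over the list alone. Camera placed the list lower with an adjusted p of 0.022, but p was 0.412 with an estimated correlation (adjusted p = 0.988), and the adjusted p was 0.0574 with forward arrays alone. The list had a median of −0.19 (−0.08 in replicate 1, −0.29 in replicate 2). The cofactor gene pbx4 was at −0.79 ± 0.72, hoxa9b at −0.62 ± 0.47, hoxb3a at −0.54 ± 0.85, meis1b at −0.45 ± 0.37 and meis1a at −0.19 ± 0.20 (SD, n = 2). Nervous system genes had negative ratios for 30 of 36, with 0 past the threshold over all genes or over the list alone and a median of −0.19. That list stood at 0.08 in replicate 1 and −0.61 in replicate 2, so its sign rested on replicate 2. The neuronal RNA-binding gene elavl4 was at −0.04 and −1.69 in the replicates, ascl1b at 0.31 and −1.59, and the glial gene gfap at −0.21 and −0.86. Camera gave an adjusted p of 0.022, p = 0.604 with an estimated correlation (adjusted p = 0.988), 0.0807 with arrays scaled to a common spread, 0.059 after quantile normalization and 0.0979 with dye-swap arrays alone.

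Erythroid genes, the most abundant blood lineage at this stage, did not pass as a list. Of 26, 19 had positive ratios with a median of 0.25 (0.48 and 0.08 in the replicates) and a camera adjusted p of 0.0518. None passed over all genes and 3 did over the list alone. The erythroid transcription factor gene gata1a was at 0.68 ± 0.46, nt5c2l1 at 0.94 ± 0.26, the haem synthesis gene hmbsb at 0.88 ± 0.20 and the globin gene hbae3 at −0.72 ± 0.16 (SD, n = 2). With an estimated correlation p was 0.503 (adjusted p = 0.988). With the preset correlation the camera call was reached after scaling (adjusted p = 0.00558), after quantile normalization (0.0199), with each probe kept apart (0.0039) and with forward arrays alone (0.0248). Of 9 blood stem and progenitor genes 0 passed, with drl at 0.58 and lmo2 at 0.44, a median of 0.19 and a camera adjusted p of 0.887.

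No gene of DNA methylation and histone modification passed among 22 (median −0.02, camera adjusted p = 0.946). dnmt1, the maintenance DNA methyltransferase gene, averaged 0.91 ± 0.16 (limma adjusted p = 0.0727, n = 2), and this mean came from 1 of its 5 probes. That probe was at 4.31, between 2.99 and 5.63 on single arrays, while the other 4 lay between −0.04 and 0.14. dnmt3ab was at −0.27 and suv39h1b at −0.29. Of 14 prostaglandin genes 0 passed, with a median of 0.09 and a camera adjusted p of 0.922. Their cyclooxygenase genes were at −0.14 (ptgs1), 0.31 (ptgs2a) and 0.16 (ptgs2b). Of 31 Wnt genes 22 had negative ratios and 0 passed (median −0.11, camera adjusted p = 0.185), with ctnnb1, the beta-catenin gene, at 0.13 in replicate 1 and −0.97 in replicate 2.

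**Figure D2:**
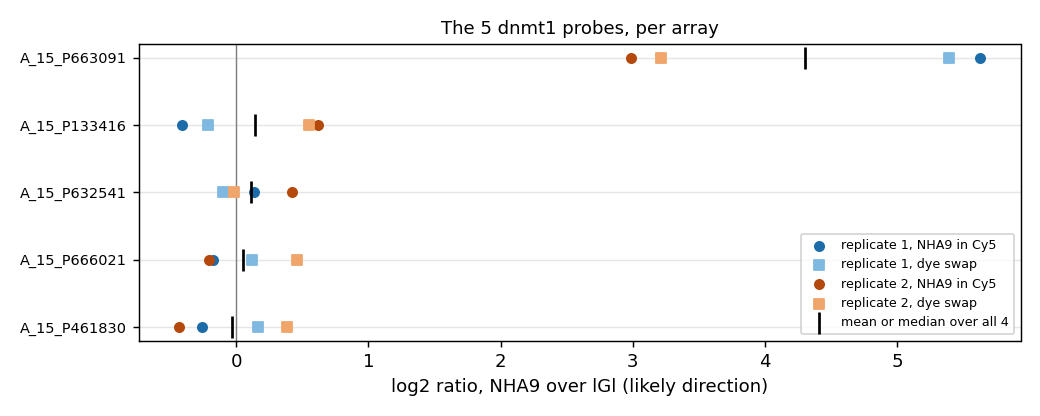
Log2 ratio of NHA9 over lGl (x axis) of the 5 dnmt1 probes, with a point for each of the 4 arrays and a bar at the mean. A single probe averages 4.31 and the other 4 average between −0.04 and 0.14.

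Of 33 heat shock and unfolded protein genes 0 passed. In all, 23 stood lower in replicate 1 than in replicate 2 and 10 stood higher, a difference that was not tested, and the list median was −0.31 in replicate 1 and 0.07 in replicate 2 (camera adjusted p = 0.291). With each probe kept apart camera placed the list lower (−0.186, adjusted p = 0.0313), while with an estimated correlation p was 0.585 (adjusted p = 0.988). hsp70l, the heat-inducible gene whose promoter family drives Cre, was at −0.94 in replicate 1 and 0.61 in replicate 2, hsp90b1 at −0.89 and −0.12, hsp90aa1.2 at −0.75 and −0.14 and atf3 at 0.34 and 0.82. hspbp1 went the other way, at −0.21 and −1.29. In the cell cycle list, kif11, a mitotic kinesin gene, was higher at 1.47 ± 0.14 (limma adjusted p = 0.000111, n = 2), as the only 1 of 48 genes past the threshold over all genes, with 2 over the list alone. The other of these 2 was ccna1, at 0.02 in replicate 1 and 1.86 in replicate 2. cdk1 and hmgb2a were at −0.69 and −0.63, and the list median was 0.02 (camera adjusted p = 0.946).

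Lists of other tissues and of housekeeping genes did not pass as main results and held 0 genes past the threshold. Their medians and camera adjusted p-values were 0.16 and 0.887 for 42 skeletal muscle genes, 0.21 and 0.843 for 9 heart genes, and 0.00 and 0.887 for 21 eye and lens genes. They were −0.01 and 0.969 for 16 endothelial genes, 0.00 and 0.887 for 29 epidermal and hatching gland genes, and 0.03 and 0.969 for 26 yolk and liver genes. The 19 pigment and neural crest genes had a median of −0.17 (adjusted p = 0.185), with 0.10 in replicate 1 and −0.40 in replicate 2. The 32 notochord, cartilage and matrix genes stood at 0.01 (adjusted p = 0.922) and the 16 somite clock and tailbud genes at 0.00 (adjusted p = 0.904). Mitochondrial energy genes (36) were at 0.02 (adjusted p = 0.922) and ribosomal protein genes (69) at −0.10 (adjusted p = 0.0686). The ribosomal list passed as lower after scaling (−0.15, adjusted p = 0.0031), after quantile normalization (−0.14, 0.0199), with each probe kept apart (−0.12, 0.0482) and with dye swaps alone (−1.05, 3.56e-49), but as higher with forward arrays alone (0.82, 5.01e-20). With an estimated correlation its p was 0.208 (adjusted p = 0.988). Skeletal muscle genes passed as higher with forward arrays alone (0.19, adjusted p = 0.0248), and epidermal (−0.247, 0.03), yolk (−0.137, 0.03) and mitochondrial genes (−0.344, 0.0113) as lower with dye swaps alone. With an estimated correlation on all 4 columns, p was 0.557, 0.653, 0.988 and 0.824 for these 4 lists. Camera, which compares a list with all other genes, pointed lower for the cell cycle, matrix, yolk and mitochondrial lists despite medians just above 0. The DNA methylation list had a median of −0.02 and a mean of 0.01, and the endothelial list a median of −0.01, a mean of 0.03 and a camera direction above 0.

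**Figure D3:**
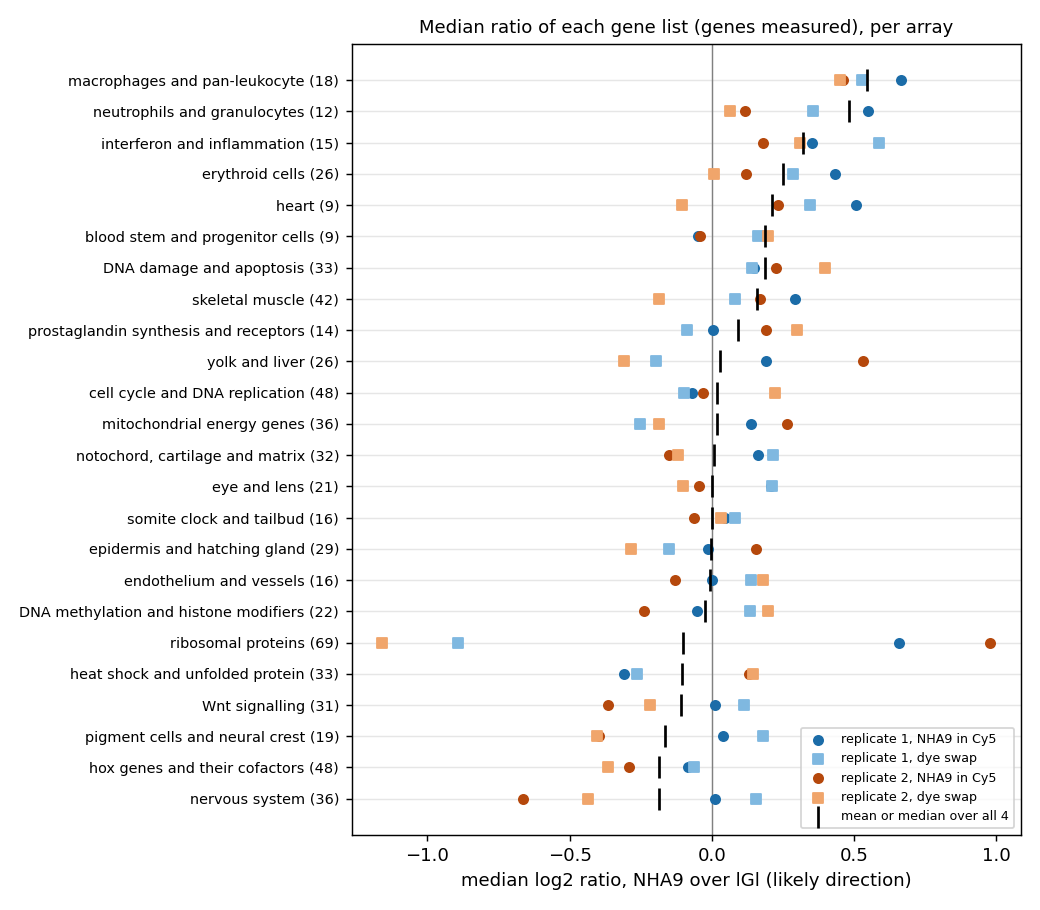
Median log2 ratio of NHA9 over lGl (x axis) of each of the 24 gene lists, with the number of measured genes in brackets, a point for each of the 4 arrays and a bar at the median of gene means. The macrophage list lies between 0.45 and 0.67 on all 4 arrays, while the ribosomal list is at 0.66 and 0.98 on forward arrays and at −0.89 and −1.16 on dye swaps.

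A reading by dye, with the sign of the dye swaps turned, gave another set of genes. limma called 1984 of 13261 items in that reading, 1306 higher and 678 lower in NHA9 embryos, of which 82 were also called in the reading above. Of its items, 73 changed at least 2-fold with one sign. Macrophage genes then had a median of 0.04 and neutrophil genes one of 0.01, while ribosomal protein genes had a median of 0.95, with 69 of 69 positive. Besides ribosomal genes, camera called the skeletal muscle, epidermal, yolk and mitochondrial lists and the DNA methylation list in that reading. None of these calls held with an estimated correlation (smallest adjusted p 0.948), a camera test that hardly any list could pass with so few replicates.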

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

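The tests of single probes and of whether the columns were deposited by dye were chosen after their results were seen, and so were both neighbour tests that leave out clone-named genes. The neighbour pairs named here were also picked after their values were seen.

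The ratio of 1984 of 13261 items differed between dye orientations in limma at an adjusted p of 0.05. Values here are the orientation effect, the forward mean minus the mean of all 4 columns, on the log2 scale. By lists, camera found a difference for ribosomal protein genes (median 0.95), mitochondrial energy genes (0.13), yolk and liver genes (0.13), epidermal and hatching gland genes (0.10), skeletal muscle genes (0.04) and DNA methylation genes (−0.11). With an estimated correlation none of them passed (smallest adjusted p 0.948), but hardly any list could pass that test with so few replicates.

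Among genes with the largest ratios, the orientation effect was 0.34 for si:ch211-191j22.3, 0.41 for atg14, 0.28 for LOC100002392, 0.57 for mrps7 and 0.30 for brf1a, all smaller than their means over the 4 columns. Among blood genes it was 0.95 for the globin gene hbae3, 0.45 for slc7a7 and 0.67 for lyz. It was 1.02 for pvalb1, 0.40 for tnni1b, 0.51 for crygm2d7, 0.35 for kdrl, 1.16 for he1.2, 1.29 for fabp1b.1 and 0.63 for lum. It was 0.53 for rpl36, 0.54 for rps3a, 0.83 for rps7, 0.93 for cox5ab, 0.29 for atf3 and 0.38 for phlda3. Negative effects were measured for cdk1 (−0.27), notch3 (−0.36), tp63 (−0.37), ahcyl1 (−0.27) and col11a2 (−0.30).

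All 69 ribosomal protein genes stood higher on forward arrays than on dye swaps. If the columns were deposited by dye, so that this difference were the NHA9 effect, the part shared by all 4 columns would be a dye effect. 2 probes of a gene correlated in the orientation effect (r = 0.363, rho = 0.153 over genes) and more in the shared part (r = 0.516, rho = 0.539). By rank the gap between the parts was wider. An absent correlation in the orientation effect would have argued against a deposit by dye, and these values do not decide it. Under such a deposit, differences between the 2 pairs of extracts would turn sign with the dyes. That part held 3.2% of the variance over probes (r = 0.169 between 2 probes of a gene). Differences between replicates that kept their sign in both orientations held 26.4% (r = 0.751). These values argue against a deposit by dye, unless the dye effect itself differed between the pairs, which was not measured. A dye effect on abundant transcripts is a candidate explanation: 61 other abundant housekeeping genes had a median orientation effect of 0.22, with 44 positive, against a 95th percentile of 0.009 in random gene sets (permutation p = 1e-04, the smallest the 10000 sets can give). That median missed the 0.3 set beforehand and lay above the 0.1 that would have argued against it, so this explanation stays open. In the reading as a single contrast, both orientations measured the same extracts, so there the difference is technical and only its link to abundance is open. No biological explanation was tested for the reading by dye.

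For 31 genes with at least 2 probes, including dnmt1, 1 probe reached 2 or more in size on the log2 scale. The median of their other probes, turned to the sign of the extreme probe, was 0.33, under 0.5 for 20 genes, at or above 1 for 9 and between for 2. These genes were picked for an extreme probe, so their other probes would lie lower in any case, and the set is mixed. Neither a change of whole transcripts nor single departing probes covers it as a whole. The extreme probe was positive in 27 of the 31 genes, among them 19 of the 20 under 0.5 and 6 of the 9 at or above 1. How far single departing probes account for the excess of higher over lower calls (271 against 105) was not tested. The 9 genes whose other probes also moved, f7i and isca1 among them, could have changed as a whole. A probe that departs alone, as with 1 transcript form, a sequence difference between the parents or a probe that binds another transcript, may account for dnmt1. These were not told apart here.

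Called genes lay side by side more often than chance. In 12 cases a called gene and the next measured gene of assembly GRCz12tu were called in the same direction, against a mean of 3.11 and a 95th percentile of 6 in 10000 random placements (permutation p = 5e-04), which is consistent with stretches of chromosome that differ between the Cre-carrying and AB parents. Copies of a gene family are another candidate. Without pairs that share a symbol stem 9 were left (95th percentile 6, permutation p = 0.0037), a result set beforehand as arguing against copies. That bound was too weak, since clone names carry no stem and c7b with c6.2 was not recognized as related either. Leaving out pairs of 2 clone-named genes gave 5 (95th percentile 6, permutation p = 0.18), and leaving out every clone-named gene gave 4 (95th percentile 5, permutation p = 0.27). Whether the clone-named neighbours are copies was not shown. By their symbols, asah1b with acsl1a (1.67 and 1.64), ufc1 with alg9 (−0.96 and −1.24) and avp with ccl27a belong to different families, so copies do not account for these pairs. Of them, ccl27a was at 2.62 in replicate 1 and −0.25 in replicate 2, and acsl1a averaged a probe at 3.57 and another at −0.30, so its call rests on 1 probe. So few unrelated pairs also arise in random placements, and whether the excess over chance came from parental haplotypes or from copies stays open. Parental genotype itself was not measured.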

How the results depend on the processing

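The median of a gene's probes, the fit without unnamed probes, the replicate block without a dye term and the count of calls with one sign were chosen after the data were seen. The count of 376 calls moved to 243 with arrays scaled to a common spread, 617 with forward arrays alone and 1984 in the reading by dye. It was 248 with a dye term and the replicate as a block (correlation 0.819), 114 with the replicate block and no dye term (0.493), and 238 without unnamed probes. The block calls were all among the 376. Dye-swap arrays alone gave 508 calls, of which 51.2% were higher against 72.1%. Other settings gave 348 to 507 calls. The causes were not tested, except that fewer items enter without unnamed probes. The count of 310 items at 2-fold moved to 480 with each probe apart, 592 with forward arrays alone, 73 by dye, 1214 at 1.5-fold and 99 at 3-fold. It ranged from 543 to 756 on leaving out either replicate, where 2 columns need share a sign. The 6 list calls became 0 with an estimated correlation and 0 with fry, tests that hardly any list could pass with so few replicates. Other settings gave 6 to 9. The median of the nervous system list ranged from −0.611 to 0.079 without either replicate. The ribosomal list turned to 0.82 with forward arrays alone.

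In the reading by dye, list medians were −0.016 (HOX genes and cofactors), −0.012 (DNA damage and apoptosis), −0.071 (interferon), 0.10 (epidermis), 0.132 (yolk), 0.948 (ribosomal) and 0.129 (mitochondrial). For all 7 camera pointed the other way. The HOX, yolk and mitochondrial medians kept their sign. The blood stem and prostaglandin medians changed sign, to −0.035 and −0.085, in lists past camera in neither reading. Genes turned to −0.081 (f7i), 0.049 (zgc:173443), 0.08 (si:ch211-251f6.7), 0.059 (LOC794425), 0.108 (fkbp16), 0.146 (si:ch211-132b12.1), 0.249 (zgc:136254), 0.083 (rnf146), 0.949 (hbae3), −0.103 (mmp13a), −0.064 (mpx), −0.20 (isg15), 0.348 (kdrl), −0.273 (ahcyl1), 1.29 (fabp1b.1), 0.532 (rpl36), 0.54 (rps3a) and 0.831 (rps7). That reading measures the orientation effect by construction. The 24 genes with the largest ratios kept their direction, and their call where tested, under every other setting run gene by gene, except 8 that lost the call with the replicate block and no dye term. Of the 10 other called genes named from lists, 6 lost the call with the block and a dye term, 8 with the block and no dye term, and 6 with arrays scaled to a common spread (slc7a7, mmp13a, mpx, bbc3, casp8 and isg15). Dye-swap arrays alone ended 3 of these calls (slc7a7, lyz and casp8) and forward arrays alone 2 (mpx and isg15). Named genes short of the threshold passed in 10 cases with forward arrays alone, 8 with dye swaps alone, 3 after quantile normalization and 1 with the median of a gene's probes.

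The gene count could not be tested on leaving out a replicate, since 1 pair of extracts leaves no residual degrees of freedom. Requiring probes in 1 array of each replicate changed nothing, since no value was missing. Signal over background, which would limit dim probes, is unknown here.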

Other observations

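The family tests and the genes in this part were chosen after their values were seen, and none of these tests was planned. Cytochrome P450 genes held several of the called genes. Of 37 with symbols starting in cyp, 6 were higher and 1 was lower in limma. The steroid synthesis genes cyp11a1.1 and cyp17a1 were at 2.96 ± 0.13 and 1.60 ± 0.06 on the log2 scale (SD, n = 2). The gene cyp17a1 encodes the enzyme that turns progestins towards androgens. In the cyp2aa cluster, cyp2aa6 was at 2.18 ± 0.37, cyp2aa1 at 1.83 ± 0.04 and cyp2aa4 at 1.19 ± 0.08, while cyp2aa3 was lower at −0.99 ± 0.15. Not past the threshold were cyp2aa8 at 0.23, cyp2aa9 at −0.01, cyp2aa12 at −0.29 and cyp2aa2 at −0.47. The gene cyp1a, a target of the aryl hydrocarbon receptor, was at 1.67 in replicate 1 and 0.34 in replicate 2. The family median was 0.22, with 0.01 in replicate 1 and 0.38 in replicate 2, and −0.02 in the reading by dye. Among 149 symbol families of at least 8 genes, camera gave this family an adjusted p of 0.000822 and p = 0.216 with an estimated correlation (adjusted p = 0.997).

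Gamma M crystallin genes of the lens were the other family past camera, at an adjusted p of 4.01e-13, but with an estimated correlation p was 0.293 (adjusted p = 0.997). All 18 had positive ratios, with a median of 0.88 (0.70 in replicate 1, 1.08 in replicate 2). In limma crygm2d18 at 1.07 (adjusted p = 0.0174) and crygm2d15 at 0.98 (adjusted p = 0.0428) passed. The median lay between 0.84 and 0.89 under the scaling settings, 1.29 with forward arrays alone and 0.46 with dye-swap arrays alone. In the reading by dye it was 0.42, with 14 of 18 positive. These genes are near-identical copies, and probes can share signal among them. The eye and lens list, which did not pass, had 11 positive and 10 negative ratios among 21 genes. Its largest ratios in size were 0.82 for crygm2d7, 0.67 for cryba1a, −0.55 for rx2 and −0.52 for pitx3.

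Several further genes called higher were picked by eye and stand for no group. The terminal complement genes c7b and c6.2 were at 1.85 ± 0.44 and 1.14 ± 0.03, and the chemokine gene cxcl20 at 2.18 ± 0.14 (limma adjusted p = 1.47e-10 for cxcl20, n = 2). Among other complement and chemokine genes, c3a.1 at 0.60 and cxcl18b at 0.20 did not pass, and ccl27a passed with 2.62 in replicate 1 and −0.25 in replicate 2. ms4a17a.9 and ms4a17a.11, of a family of membrane proteins, were at 2.29 ± 1.33 and 1.94 ± 0.13, while ms4a17a.5 at −0.38 and ms4a17a.7 at −0.36 did not pass. ms4a17a.9 was at 3.23 in replicate 1 and 1.35 in replicate 2. The vasopressin gene avp was at 1.60 ± 0.59, and the nuclear receptor gene nr0b2a at 1.89 ± 1.77, with 3.14 in replicate 1 and 0.64 in replicate 2.

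The lowest ratios of all belonged to unnamed probes. A_15_P550177 was at −7.61 ± 0.02 and A_15_P401555 at −7.51 ± 0.55 (SD, n = 2), each at or below −6.93 on all 4 arrays. The transcripts behind these probes are not named in the tables used here, and whether either channel was near background is unknown.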
